A study of Drosophila melanogaster with 2 samples.

How the data were processed

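Total RNA of whole Drosophila melanogaster embryos was compared on 2 two-colour arrays, named A and B in the labels. Per the labels, hemocyte plus embryos were wild type and hemocyte minus embryos were serpent (srp) mutants. RNA was extracted with Trizol, cleaned on RNeasy columns and labelled by amino-allyl reverse transcription, per the labels. On array A the Cy3 channel held unwounded hemocyte minus RNA and the Cy5 channel unwounded hemocyte plus RNA. On array B the dyes were swapped, and its channel labels do not repeat the word unwounded. The labels do not say whether the arrays held separate RNA extracts. If they held the same 2 extracts, the arrays are 1 biological replicate and no p-value below measures biological spread. In either case the p-values of single genes measure only the spread between these 2 arrays. The p-values of permutation tests, and of gene lists and families at a preset correlation, set genes against other genes.

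The authors deposited 1 value per probe and array. All deposited values lie below 0, from -31.17 to -0.01 on array A and from -30.98 to -0.01 on array B, with medians of -0.989 and -1.021. The values have the form of a linear dye ratio multiplied by -1: the size of each deposited value has a median near 1, its log2 is far less skewed than the size itself, and sizes that are high on one array are low on the other. The 12 probes whose ratio was at least 8-fold on both arrays had products of the deposited sizes between 0.395 and 1.54, where an ideal dye swap gives 1. The scanner, the background correction, the normalization, the reason for the minus sign and the dye in the numerator are not given in the sources used here. No channel intensities were used, so signal over background is unknown. The number of arrays limits the precision.

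The log2 of the size of each deposited ratio was taken, the ratio of one array was turned against the other according to the dyes in the labels, and each array was centred on its median over all probes. Before turning, the log2 ratios of the arrays had Pearson r = -0.689 across probes, as opposite dye orientations give. The sign that remains open is common to both arrays. The direction laid down before the data were examined was hemocyte plus over hemocyte minus, with the hemocyte markers as a check only. A first look took Cy5 as the numerator and put those markers clearly on the hemocyte minus side. Positive values are therefore given here with Cy3 as the numerator on both arrays, a choice made after the markers had been seen. Every signed value changes its sign, and keeps its size and p, if Cy5 was the numerator. Values are described by side: the hemocyte side (positive) is the side of the hemocyte markers, and the opposite side is negative.

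The table held 12144 probes, with 137 values missing on array A and 128 on array B. The platform annotation gave 1 gene symbol for 9917 probes and several for 625, and 1602 probes were not named in it. Of the probes with 1 symbol, 9746 had a gene identifier found in the RefSeq gene table of the Release 6 assembly, no symbol changed through that match, and 171 kept the symbol of the annotation. Probes with several symbols or none entered no gene result. Values on both arrays existed for 11964 probes, of which 9793 had 1 symbol. The probes of a gene were averaged, which gave 8224 genes, 1297 of them with 2 or more probes. For 32 genes the probes differed by more than 1 in mean log2 ratio. Probe names have the form of cDNA clone names, and long cDNA probes can bind transcripts of close relatives. Values of the near-identical Amy and Hsp70 copies are therefore uncertain as to which copy was measured. Binding between more diverged relatives, such as PPO or Gst genes, was not examined.

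Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept only) against a log2 ratio of 0, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 2 arrays left 1 residual degree of freedom per gene, and moderation added 5.01 prior degrees of freedom with a prior SD of 0.168. A dye effect cancels in the mean of the 2 arrays and adds to the residual. Beside the test, genes at least 2-fold from 1 on each array were counted. Errors after ± are SDs of the 2 arrays. The procedure was tested on data simulated for 8224 genes and 2 arrays, 20 times: it recovered 29.5% of genes changed 1.5-fold, 93% at 2-fold, 99.9% at 4-fold and 100% at 8-fold, and 7.46% of its calls were false. That share is above the nominal rate of the threshold. The simulation changed a far smaller share of genes than passed in the data, with independent noise from the fitted prior. These rates therefore need not hold for the data.

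A set of 22 gene lists (cell types of the embryo, processes and protein classes) and the rule for named genes were fixed before the data were examined. The rule named the 12 genes highest and the 12 lowest by mean log2 ratio among those past the limma threshold with one sign on both arrays, srp, every measured plasmatocyte and crystal cell marker, and the 2 highest and 2 lowest members of each other list. Other members named as examples of a list were chosen after their values were seen. Lists were tested with camera of limma (two-sided, preset correlation 0.01, adjusted over the 22 lists). At the preset correlation camera sets the genes of a list against all other genes, so its p does not measure replication between arrays. With an estimated correlation the test has 1 residual degree of freedom, and then no list passed 0.05. Among the lists past the preset test, the estimate ran from -0.077 for muscle to 0.200 for cell cycle. It was 0.150 for cuticle and 0.148 for cytosolic ribosomal proteins. Where the true correlation exceeds 0.01, the p at the preset correlation is too low. The count of members past the threshold is given for adjustment over all genes and for adjustment over the list alone. Each list's median was also set among 10000 random gene lists of its size.

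The alternatives tried were no centring, arrays scaled to one median absolute deviation, robust moderation, limma's treat against 1.2-fold, each probe tested alone, values at the lowest size of 0.01 left out, array B turned the other way, other fold thresholds, single arrays, means in place of medians, Spearman's rho and the probe with the largest change for each gene. Leaving out probes whose identifiers end in ReAmp, rdnd or dupe was added after the data were examined. Symbol families of at least 5 genes were also tested with camera after the data were examined. Calculations outside R used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.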

Results

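The data were 2 dye-swapped two-colour arrays, A and B, each with RNA of hemocyte plus (wild type) Drosophila embryos in one channel and RNA of hemocyte minus (serpent mutant) embryos in the other. Hemocytes are the blood cells of the fly, and serpent (srp) encodes a GATA transcription factor needed to form embryonic hemocytes and the fat body. The comparison asked which transcripts differ between wild type embryos and these mutants, so a difference need not come from the missing hemocytes. Ratios on both arrays were available for 8224 genes. Across these genes the turned log2 ratios of the arrays had Pearson r = 0.746 and Spearman rho = 0.561, and 68.6% of genes had one sign on both arrays. Genes are not independent replicates, so no p is attached to these values. The median absolute difference between the arrays was 0.17 in log2 ratio.

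The direction of the ratios is not settled by the labels, since the dye in the numerator is not given in the sources used here. The prophenoloxidase gene PPO1, a marker of crystal cells, had a mean log2 ratio of 4.87 ± 0.08 (SD, n = 2 arrays) with Cy3 as the numerator and -4.87 with Cy5 as the numerator. With Cy3 as the numerator, 24 of the 27 measured plasmatocyte and crystal cell markers were positive, and positive values then mean higher in hemocyte plus embryos. Since the labels call the mutants hemocyte minus, this reading is the likely one. It was taken after the markers had been seen, so their side is no independent evidence of direction. Positive values are called the hemocyte side and negative values the opposite side, and all signs turn if Cy5 was the numerator.

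Prophenoloxidase genes were 3 of the 12 genes with the highest ratios on the hemocyte side. PPO1 differed 29.2-fold (limma adjusted p = 7.51e-05). PPO2, which encodes another prophenoloxidase of crystal cells, had a log2 ratio of 3.71 ± 0.28, a 13.1-fold difference (adjusted p = 0.000252). PPO3, known from lamellocytes, lay at 2.55 ± 0.01, and whether its probe also binds transcripts of PPO1 or PPO2 was not examined. The scavenger receptor gene ninaD, known for carotenoid uptake, differed 17.8-fold at 4.15 ± 0.43 (adjusted p = 0.000252). The other genes among the 12 highest were the cytochrome P450 gene Cyp12c1 (12.2-fold), smp-30 (8.15-fold), CG17109 (8.08-fold), NtR (7.53-fold), CG6733 (7.46-fold), CG8160 (7.22-fold), CG42369 (5.89-fold) and the growth-blocking peptide gene Gbp2 (5.78-fold), none of which is in a fixed list. CG42369 had the widest spread among the 12, at 2.56 ± 0.80.

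On the opposite side, genes of Tweedle proteins, which are part of the cuticle, made up 4 of the 12 genes with the lowest ratios. TwdlM lay at -2.70 ± 0.60 (6.52-fold, limma adjusted p = 0.000996), TwdlB at -2.38 ± 0.45, TwdlN at -2.37 ± 0.53 and TwdlL at -2.35 ± 0.43. The metallothionein gene MtnA, whose product binds metal ions, lay at -2.57 ± 0.04 (5.92-fold, adjusted p = 0.000252). The lowest ratio belonged to CG14644 at -3.82 ± 0.96 (14.1-fold, adjusted p = 0.00111), with -3.14 on array A and -4.50 on array B. CG7299 followed at -3.28 ± 0.23 (9.69-fold), then CG5171 at -2.91 ± 0.17 (7.49-fold), CG17325 at -2.89 ± 0.19 (7.42-fold) and CG11737 at -2.81 ± 0.46 (7.02-fold). CG14147 and CG11382 completed the 12 at -2.34 ± 0.43 and -2.31 ± 0.28.

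**Figure D1:**
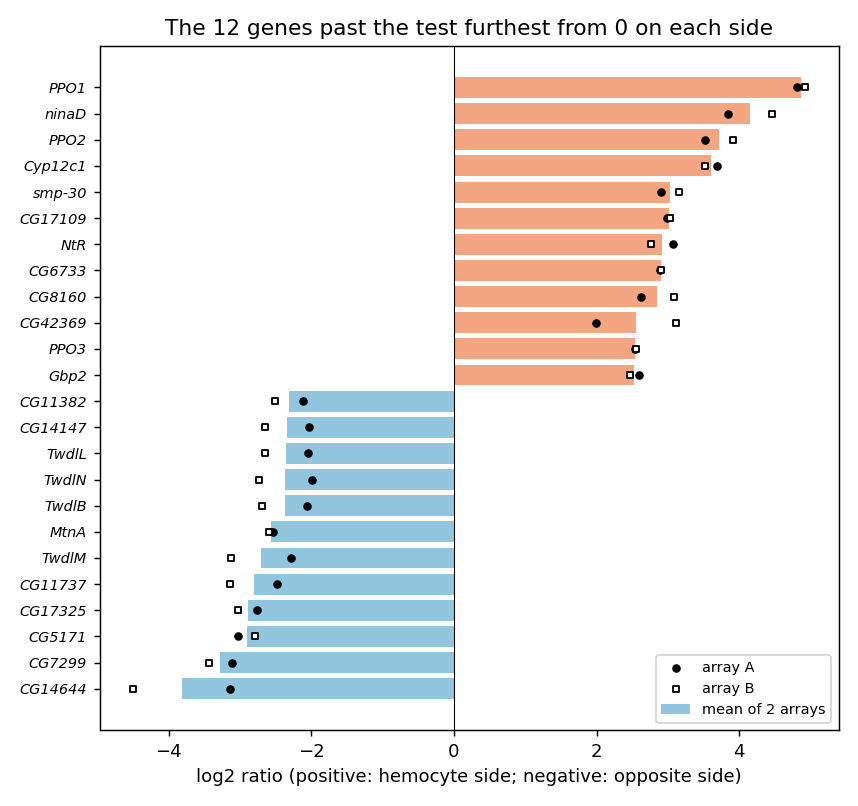
Log2 ratios (horizontal axis) of the 12 genes past the limma threshold that lie furthest from 0 on each side, with bars for the mean of 2 arrays, filled circles for array A and open squares for array B. PPO1 has the highest mean at 4.87 and CG14644 the lowest at -3.82, and the 2 arrays lie on one side of 0 for each gene shown.

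The gene mutated in the hemocyte minus embryos, srp, had log2 ratios of 0.15 on array A and 0.36 on array B. Its mean of 0.26 ± 0.15 did not pass the limma test (adjusted p = 0.221). The allele and the position of the probe relative to its lesion are not given in the sources used here, so the value does not check the genotype.

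Across all 8224 genes, 1106 (13.4%) passed the limma threshold, with 433 on the hemocyte side and 673 on the opposite side, and each of them had one sign on both arrays. The count at an unadjusted p under 0.05 was 2264. The genes past the threshold had a median difference of 1.67-fold, and the smallest was 1.36-fold. At least 2-fold on both arrays were 246 genes, 96 on the hemocyte side and 150 on the opposite side, and all 246 also passed limma. In opposite directions on the 2 arrays, the pattern that a dye effect would leave, no gene was at least 2-fold and 16 genes were at least 1.5-fold, against 623 in one direction. Among single probes, 4 were at least 2-fold in opposite directions and 362 in one. Tested against a 1.2-fold difference rather than 0, 535 genes passed. With array B alone, 252 genes were at least 2-fold on the opposite side, against 172 with array A alone.

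**Figure D2:**
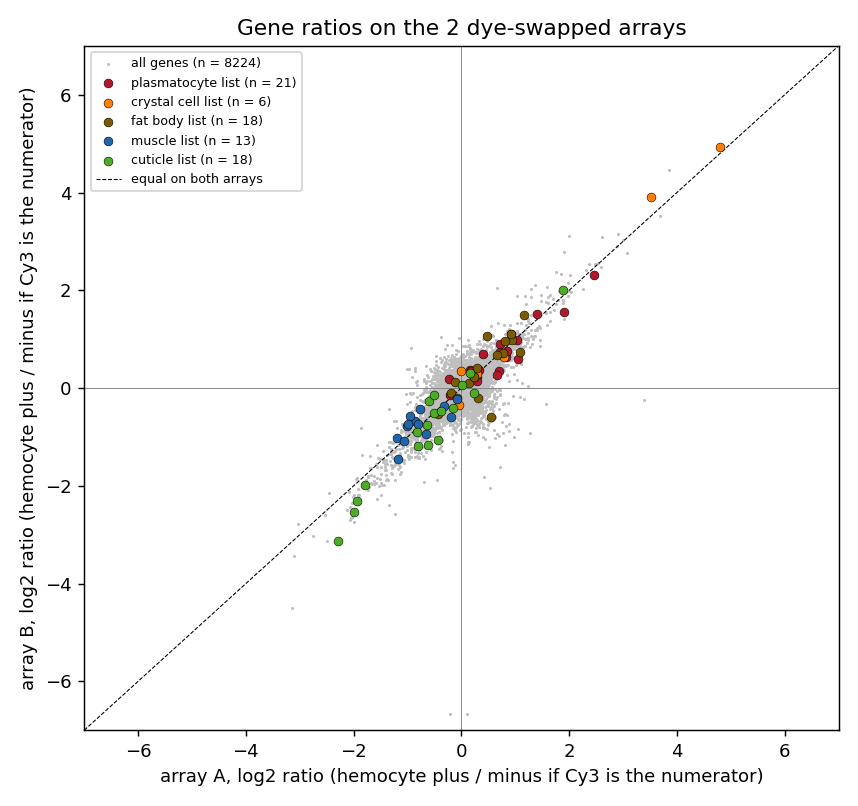
Log2 ratio of each gene on array A (horizontal axis) and array B (vertical axis), with all 8224 genes in grey and the members of 5 gene lists in colour; the dashed line marks equal values. Plasmatocyte, crystal cell and fat body genes extend to the upper right (hemocyte side), and muscle and cuticle genes to the lower left (opposite side).

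Plasmatocytes are the macrophages of the embryo, and 11 of the 21 measured genes of their list passed on the hemocyte side and none on the opposite side. Adjusted over the list alone, 14 passed on the hemocyte side and 0 on the opposite side. The highest was Ppn, which encodes the extracellular matrix protein papilin, at 2.39 ± 0.10 (5.23-fold, limma adjusted p = 0.000318). NimC4, a receptor for apoptotic cells, lay at 1.73 ± 0.24 and the peroxidasin gene Pxn at 1.46 ± 0.08. The collagen IV gene Col4a1 and the phagocytosis receptor gene NimC1 both lay at 1.01, with SDs of 0.13 and 0.05. SPARC (0.82 ± 0.32), the scavenger receptor gene crq (0.81 ± 0.12), Glt (0.80 ± 0.06), the growth factor receptor gene Pvr (0.73 ± 0.01), NimB4 (0.73 ± 0.13) and the hemolectin gene Hml (0.55 ± 0.21) also passed. The ferritin genes Fer1HCH (0.52 ± 0.25, adjusted p = 0.0525) and Fer2LCH (0.47 ± 0.27), sn (0.35 ± 0.03), zfh1 (0.26 ± 0.11), ush (0.25 ± 0.04), vkg (0.22 ± 0.10), drpr (0.22 ± 0.05), eater (-0.03 ± 0.29) and Tig (-0.17 ± 0.05) did not, nor did srp. NimC1 lay at 0.39 and no longer passed (adjusted p = 0.0829) when probes marked ReAmp, rdnd or dupe were left out, and Tig then passed on the opposite side at -0.67. With the probe of largest change Glt lay at 1.52. Both ferritin genes passed without centring, and Fer1HCH also with scaled arrays. The list's median was 0.55 (camera adjusted p = 2.3e-09, and adjusted p = 0.63 with an estimated correlation).

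Of the 6 measured crystal cell genes, PPO1, PPO2 and the malic enzyme gene Men (0.71 ± 0.10, limma adjusted p = 0.0111) passed on the hemocyte side, both over all genes and adjusted over the list alone. The transcription factor genes klu (0.28 ± 0.00) and peb (0.17 ± 0.25) and Ahcy (-0.20 ± 0.22) did not pass. The median was 0.50 and the mean 1.59 (camera adjusted p = 0.000701, and adjusted p = 0.63 with an estimated correlation).

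Fat body genes, whose tissue also requires srp, lay mostly on the hemocyte side. Of 18 measured, 8 passed there and 1 on the opposite side, and adjusted over the list alone 9 and 1. The lipoprotein genes apolpp (1.33 ± 0.24, limma adjusted p = 0.00209), Apoltp (0.96 ± 0.02) and Mtp (0.91 ± 0.24) and the lipase gene bmm (0.74 ± 0.04) were among them, as was Col4a1, which the plasmatocyte list shares. Gpdh1 passed on the opposite side at -0.48 ± 0.07, and Lsp2 lay at -0.15 ± 0.07 without passing. The median was 0.29 (camera adjusted p = 0.000356, and adjusted p = 0.63 with an estimated correlation).

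Basement membrane genes split. Of 18 measured, 8 passed on the hemocyte side and 2 on the opposite side, and adjusted over the list alone 9 and 2. The list shares 7 genes with the plasmatocyte list; of its other 11, 3 passed on the hemocyte side and 2 on the opposite side, with a median of -0.09. The collagen-modifying enzyme genes Plod (1.18 ± 0.01) and PH4alphaEFB (0.64 ± 0.24) and the laminin gene LanA (0.60 ± 0.16) lay on the hemocyte side. Mp, which encodes a collagen of another type, lay at -0.90 ± 0.05 and the metalloproteinase inhibitor gene Timp at -0.68 ± 0.07. The median of the whole list was 0.36 (camera adjusted p = 0.00923, and adjusted p = 0.63 with an estimated correlation). It was 0.17 with each probe taken on its own, 0.53 on array A and 0.25 on array B.

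Of 7 measured heat shock genes 6 passed on the hemocyte side, also adjusted over the list alone, with the small heat shock protein genes Hsp27 at 1.12 ± 0.01 and Hsp26 at 1.09 ± 0.03 (limma adjusted p = 0.00215 and 0.00237) and Hsp68 at 0.47 ± 0.02, while stv lay at 0.00 ± 0.11. The list leaves out 5 measured Hsp genes (Hsp110 and 4 Hsp60 genes), none of which passed, and all 9 Hsp genes as a group, formed after the values were seen, had a median of 0.16 and did not pass camera (adjusted p = 0.08). Hsp68 no longer passed with the probe of largest change (adjusted p = 0.05, just above the threshold before rounding) or without the marked probes (adjusted p = 0.0503). It has 1 probe and its ratio was the same in both settings, so only the moderation and the adjustment over all genes changed. The heat shock median was 0.60 (camera adjusted p = 6.23e-05, and adjusted p = 0.63 with an estimated correlation). Of 17 glutathione and oxidative stress genes, 7 passed on the hemocyte side, and all 7 encode glutathione S-transferases, led by GstE3 at 1.85 ± 0.06 (adjusted p = 0.000578) and GstD3 at 1.43 ± 0.12. The 22 measured Gst genes of all classes, grouped after the values were seen, had 7 on the hemocyte side and 3 on the opposite side, GstZ1 (-0.63), GstE13 (-0.61) and GstT3 (-0.52), and did not pass camera (median 0.16, adjusted p = 0.0796). None of the 17 listed genes passed on the opposite side over all genes, and adjusted over the list alone 7 and 2 passed, the 2 being Prx6b (-0.53 ± 0.29) and Trx2 (-0.46 ± 0.11). These 2 also passed over all genes without centring and with scaled arrays. The median of this list was 0.10 and its mean 0.41 (camera adjusted p = 0.0101, and adjusted p = 0.63 with an estimated correlation). On single arrays the median was 0.30 (A) and 0.20 (B).

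Of 16 cell cycle genes, the mitotic cyclin genes CycB (0.80 ± 0.08) and CycB3 (0.78 ± 0.11) passed on the hemocyte side, with the same count adjusted over the list alone, and 15 of the 16 were above 0. The DNA polymerase clamp gene PCNA lay at 0.01 ± 0.35 and fzy at -0.18 ± 0.12. With the probe of largest change fzy lay at -0.70 and passed on the opposite side (limma adjusted p = 0.0279). The median was 0.29 (camera adjusted p = 0.000299, and adjusted p = 0.63 with an estimated correlation).

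Muscle genes lay on the opposite side: all 13 measured were below 0, and 10 passed there and none on the hemocyte side. Adjusted over the list alone, 12 passed. The muscle LIM protein gene Mlp60A lay at -1.32 ± 0.20 (2.49-fold, limma adjusted p = 0.00195), the paramyosin gene Prm at -1.11 ± 0.12, Act87E at -0.35 ± 0.04 and Msp300 at -0.15 ± 0.10, and the last 2 did not pass. With the probe of largest change Msp300 lay at -0.61 (limma adjusted p = 0.055). The median was -0.77 (camera adjusted p = 2.77e-08, and adjusted p = 0.63 with an estimated correlation).

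Of 18 cuticle genes, 10 passed on the opposite side and 1 on the hemocyte side, and adjusted over the list alone 12 and 1. TwdlM and TwdlD (-2.27 ± 0.39, limma adjusted p = 0.000771) were the lowest, and Cpr56F lay at -2.12 ± 0.26. Cpr49Ac passed on the hemocyte side at 1.95 ± 0.08 (3.86-fold), and Ccp84Ag lay at 0.24 ± 0.10 without passing. The median was -0.60 (camera adjusted p = 2.38e-05, and adjusted p = 0.63 with an estimated correlation).

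Genes of cytosolic ribosomal proteins lay slightly to the opposite side as a list, with no single gene past the test. None of 31 passed limma on either side, over all genes or adjusted over the list alone, and 29 were below 0. The lowest were RpS5b (-0.47 ± 0.15) and RpL34a (-0.33 ± 0.16), and the highest were RpLP1 (0.08 ± 0.00) and RpL29 (0.47 ± 0.98). RpS5b passed limma without centring and with scaled arrays. The median was -0.18 (camera adjusted p = 0.00285, and adjusted p = 0.648 with an estimated correlation). It was -0.13 on array A and -0.29 on array B.

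**Figure D3:**
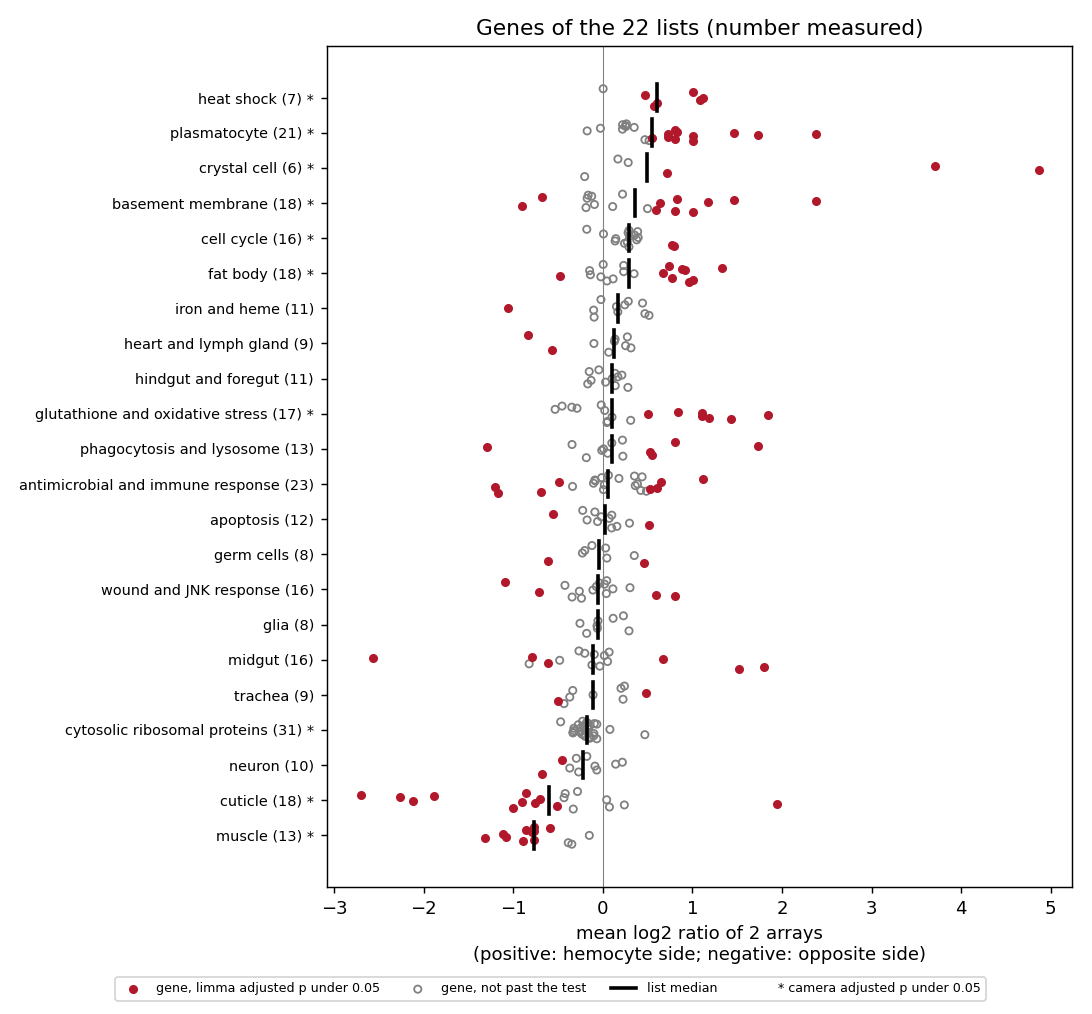
Mean log2 ratio of 2 arrays (horizontal axis) of each measured gene in the 22 gene lists, with filled circles for genes past the limma threshold, open circles for the others, black bars for list medians and asterisks for lists with a camera adjusted p under 0.05 at the preset correlation. Medians run from -0.77 for muscle to 0.60 for heat shock.

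The other 12 lists did not pass camera. Midgut genes went both ways, with 3 past limma on each side. The amylase genes Amy-p (1.80 ± 0.01) and Amy-d (1.52 ± 0.49), near-identical copies that one probe may not separate, lay on the hemocyte side and MtnA on the opposite side. Jon65Aiii lay at -0.82 ± 0.64 and did not pass, except without centring and with scaled arrays. The midgut median was -0.11 (camera adjusted p = 0.505), and adjusted over the list alone 3 genes passed on the hemocyte side and 5 on the opposite side.

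Of 10 neuron genes, the glutamate decarboxylase gene Gad1 (-0.68 ± 0.02) and the neuronal synaptobrevin gene nSyb (-0.46 ± 0.09) passed limma on the opposite side, with the same count adjusted over the list alone. The call of nSyb ended with the probe of largest change (adjusted p = 0.0561) and without the marked probes (adjusted p = 0.0565). With 1 probe, nSyb kept its ratio in both settings, and only the moderation and the adjustment over all genes changed. The neuron median was -0.22 (camera adjusted p = 0.132); it passed with each probe tested alone (adjusted p = 0.0304) and with the probe of largest change (adjusted p = 0.0376), in a range of 0.0304 to 0.63 over the alternatives. The neuron genes futsch (0.22 ± 0.06) and elav (0.14 ± 0.32) did not pass. None of 8 glia genes passed over all genes or adjusted over the list alone, from moody at -0.26 ± 0.03 and Gli at -0.18 ± 0.15 to wrapper at 0.23 ± 0.04 and Gs2 at 0.29 ± 0.05. The glia median of -0.06 (camera adjusted p = 0.911) differed in sign from the mean and the test. Among 9 trachea genes, pio (0.48 ± 0.17) passed on the hemocyte side and emp (-0.50 ± 0.15) on the opposite side, and adjusted over the list alone 1 and 3 passed. Both calls ended with the probe of largest change (limma adjusted p = 0.0605 for pio and 0.0505 for emp) and without the marked probes (0.0607 and 0.0508). Each gene has 1 probe and kept its ratio, so only the moderation and the adjustment over all genes changed. The trachea median was -0.11 (camera adjusted p = 0.816), with verm at 0.24 ± 0.27 and Gasp at -0.43 ± 0.23 not past the threshold over all genes.

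None of 11 hindgut and foregut genes passed, also adjusted over the list alone, from cad (-0.17 ± 0.11) and otp (-0.15 ± 0.10) to lin (0.21 ± 0.15) and bin (0.28 ± 0.34), and the median was 0.10 (camera adjusted p = 0.691). Of 9 heart and lymph gland genes, pericardin (prc, -0.84 ± 0.11) and cubilin (Cubn, -0.56 ± 0.14) passed limma on the opposite side, also adjusted over the list alone. The heart list had Him at 0.31 ± 0.28 and pnr at 0.27 ± 0.13, and its median of 0.13 (camera adjusted p = 0.866) differed in sign from its mean of -0.04. Of 8 germ cell genes, aub (0.46 ± 0.01) and gcl (-0.61 ± 0.14) passed on different sides, while ovo (0.35 ± 0.03) and piwi (-0.23 ± 0.05) did not. The call of aub ended with the probe of largest change (limma adjusted p = 0.0502) and without the marked probes (0.0505). Its ratio, from 1 probe, stayed the same, and only the moderation and the adjustment over all genes changed. Adjusted over the list alone, 2 germ cell genes passed on the hemocyte side and 1 on the opposite side, and the median was -0.04 (camera adjusted p = 0.911).

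Among 13 phagocytosis and lysosome genes, 4 passed limma on the hemocyte side, led by NimC4 and crq, and 1 on the opposite side, also adjusted over the list alone. The latter was the lysozyme gene LysX at -1.29 ± 0.27 (adjusted p = 0.0026), and Npc2a lay at -0.34 ± 0.26. The median was 0.10 (camera adjusted p = 0.147); with each probe tested alone the list passed (adjusted p = 0.00953), in a range of 0.00953 to 0.63 over the alternatives. Of 12 apoptosis genes, Dark (0.52 ± 0.16) and the TNF ligand gene egr (-0.56 ± 0.14) passed on different sides, also adjusted over the list alone, while Dcp-1 (0.30 ± 0.02) and skl (-0.22 ± 0.02) did not, and the median was 0.03 (camera adjusted p = 0.866).

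The 23 antimicrobial and immune response genes had 4 past limma on each side. The Toll pathway protease gene grass (1.11 ± 0.15) and the receptor gene Tl (0.65 ± 0.13) were highest, and PGRP-LA (-1.20 ± 0.06) and BomS2 (-1.17 ± 0.10) lowest. Adjusted over the list alone, 10 passed on the hemocyte side and 5 on the opposite side, and the median was 0.06 (camera adjusted p = 0.294). Of 16 wound and JNK response genes, Gadd45 (0.81 ± 0.24) and Hph (0.59 ± 0.16) passed on the hemocyte side, and the tyrosine hydroxylase gene ple (-1.09 ± 0.00) and Pvf1 (-0.71 ± 0.03), which encodes a ligand of Pvr, on the opposite side. Adjusted over the list alone 2 and 3 passed, and the median was -0.05 (camera adjusted p = 0.567). Of 11 iron and heme genes, Mco1 passed on the opposite side at -1.06 ± 0.05 (limma adjusted p = 0.00255) and Irp-1B lay at -0.10 ± 0.19. Adjusted over the list alone 3 iron genes passed on the hemocyte side and 1 on the opposite side, and the median was 0.17 (camera adjusted p = 0.264).

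Among random gene lists of the same size, the medians of plasmatocyte, crystal cell, fat body, basement membrane, heat shock and cell cycle genes lay at percentile 100. The glutathione and oxidative stress median lay at 92.4 and so was not extreme among random lists, although the list passed camera. Muscle and cuticle genes lay at percentile 0.0 and cytosolic ribosomal proteins at 0.1. Of the lists that did not pass camera, neuron genes lay at 1.4, iron and heme genes at 97.3 and the other 10 between 7.8 and 91.1.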

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

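The comparison of unnamed probes with control-named spots was chosen after the values were seen. Probes without a single gene symbol entered no gene result. Of 2068 such probes measured on both arrays, 60 were at least 2-fold from 1 on both, 30 on the hemocyte side and 30 on the opposite side. Among all 11964 probes measured on both arrays 362 were, a similar share, so the count of unnamed probes is not unusual. The largest was 32.1-fold, the probe SD15022 at a mean log2 ratio of -5.00, followed by SD21648 at -4.63. None of 103 control-named spots was at least 2-fold on both arrays in one direction. The largest absolute mean of a control-named spot was 3.61, from a spot at -0.55 on array A and at -6.67 on array B, where its deposited size was the smallest in the table. It was exceeded by 4 of the unnamed probes and by 4 of the 24 named genes furthest from 0. Without that spot the largest was 1.11, which all 24 exceeded. No biological explanation was tested for these probes.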

How the results depend on the processing

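The choices to leave out probes marked ReAmp, rdnd or dupe, and, for gene lists, to use the probe with the largest change or to leave out values at the floor, were made after the data were examined; the other alternatives were planned. The count of 1106 genes stayed between 984 and 1332 without centring, with scaled arrays, with robust moderation, with each probe tested alone, without values at the floor and without the marked probes. Of the 1106 genes, all were kept without centring, with scaled arrays and without floor values, 1101 with robust moderation, 993 with the probe of largest change, 978 without the marked probes and 976 with each probe tested alone, where 1170 probes of 1039 genes passed. The share on the hemocyte side was 39.2%, and 43.8% without centring. Against a 1.2-fold difference 535 genes passed, 199 on the hemocyte side and 336 on the opposite side. With array B turned the other way limma called 0 genes, 0 on either side, since that setting sets the arrays against each other. At 1.5-fold on both arrays there were 623 genes (229 and 394), and at 3-fold 82 (38 and 44). Single arrays gave 303 to 369 genes at 2-fold, with 117 to 131 on the hemocyte side and 172 to 252 on the opposite side. Spearman's rho was 0.561 against Pearson's r of 0.746. The cause was not tested for these changes.

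With an estimated correlation none of the 10 lists past camera kept its call, and their medians stay as they are by construction: 0.55 for plasmatocyte, 0.50 for crystal cell, 0.36 for basement membrane, 0.29 for fat body, 0.60 for heat shock, 0.10 for glutathione, 0.29 for cell cycle, -0.77 for muscle, -0.60 for cuticle and -0.18 for ribosomal proteins. That test has 1 residual degree of freedom. All 10 stayed past 0.05 under the 6 other alternatives with a test of their own. The neuron list passed with each probe tested alone (median -0.11) and with the probe of largest change (-0.36), and the phagocytosis list with each probe tested alone (0.22); the cause was not tested. On single arrays, where no test is possible, medians ran from 0.60 to 0.69 for plasmatocyte, 0.49 to 0.53 for crystal cell, 0.32 to 0.39 for fat body, -0.0877 to -0.0518 for midgut, -0.0502 to 0.105 for hindgut and foregut, -0.315 to -0.306 for neuron, -0.0526 to 0.0222 for glia, 0.10 to 0.12 for heart, -0.0819 to -0.0351 for germ cells, 0.11 to 0.19 for phagocytosis, 0.0198 to 0.0569 for apoptosis, 0.66 to 0.71 for heat shock and 0.20 to 0.30 for glutathione. The other lists ran from 0.25 to 0.53 for basement membrane, 0.25 to 0.35 for cell cycle, -0.86 to -0.73 for muscle, -0.63 to -0.56 for cuticle, -0.287 to -0.129 for ribosomal proteins, -0.13 to -0.08 for trachea, 0.04 to 0.12 for antimicrobial, -0.0906 to 0.0021 for wound and JNK and 0.0649 to 0.27 for iron and heme; wound, hindgut and glia medians thus differed in sign between the arrays.

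Of 120 named genes, 73 passed limma. All 73 kept the call without centring, with scaled arrays, with robust moderation and without floor values, 68 with the probe of largest change, 67 without the marked probes, 55 against a 1.2-fold difference and 0 with array B turned. Without centring, with scaled arrays, with the probe of largest change or without the marked probes, 8 others gained a call and 0 reversed. The calls lost with the probe of largest change were those of nSyb, emp, pio, aub and Hsp68, each with 1 probe and an unchanged ratio. Each ratio sets both conditions of an array against each other, so the fit is paired by array, and leaving out an array leaves no residual degree of freedom. Signal over background is unknown, so no limit for dim probes can be given.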

Other observations

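Tests of symbol families, and all tests of explanations apart from that of genes near srp, were chosen after the values were seen. Families were groups of at least 5 genes with one symbol stem, and 9 of 113 passed camera at the preset correlation, while all 9 had an adjusted p of 0.933 with an estimated correlation. The 9 family medians kept their sign without centring and with scaled arrays. The Tweedle cuticle genes (Twdl) were the lowest: 14 of 15 passed limma on the opposite side, with a median of -1.87 (camera adjusted p = 1.25e-14) and only TwdlP, at -0.71, not past the threshold. TwdlM, TwdlE and TwdlD are also in the cuticle list, and TwdlM, TwdlB, TwdlN and TwdlL were already among the 12 lowest genes. Of 14 Osiris genes (Osi), which encode membrane proteins of insects, 13 passed on the opposite side with a median of -0.85 (camera adjusted p = 4.37e-10), the lowest being Osi19 at -1.76. Of 27 tetraspanin genes (Tsp), 13 passed on the opposite side with a median of -0.46 (camera adjusted p = 5.01e-06), led by Tsp42En at -1.70 and Tsp74F at -1.49.

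Cuticle protein genes of the Cpr family went both ways, 16 of 35 on the opposite side and 3 on the hemocyte side, with a median of -0.32 (camera adjusted p = 0.000501). Of these, Cpr49Ac, Cpr49Ae, Cpr50Cb, Cpr56F, Cpr76Bd and Cpr92F are also in the cuticle list. The dpr genes, which encode immunoglobulin-domain proteins of neurons, had 6 of 14 past limma on the opposite side (median -0.45, camera adjusted p = 0.00111). Subunits of the vacuolar proton pump (Vha) had 5 of 18 on the opposite side (median -0.35, camera adjusted p = 0.0021), and the obst family 2 of 5 (median -0.37, camera adjusted p = 0.0362). The cuticle list shares obst-A and obst-B with the obst family. Genes of mitochondrial ribosomal proteins (mRp) showed a small shift, with a median of -0.25 over 63 genes (camera adjusted p = 1.19e-06) and 4 past limma, of which mRpS34 was lowest at -0.91. The Nimrod genes (Nim), which encode phagocytosis receptors and relatives, were the only one of the 9 families on the hemocyte side, with 4 of 5 past limma and a median of 0.95 (camera adjusted p = 0.00338). Of these 4, NimC1, NimC4 and NimB4 are also in the plasmatocyte list, and NimC1 falls to 0.39 without its call when probes marked ReAmp, rdnd or dupe are left out. NimB2, in no fixed list, lay at 0.95, and NimB1 had log2 ratios of 0.52 on array A and -1.21 on array B.

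The hemocyte markers lay on the hemocyte minus side if Cy5 was the numerator. Channel labels exchanged on a single array would make the deposited ratios of the arrays correlate above 0, and r was -0.689, which argues against that. With a Cy3 numerator 88.9% of the 27 markers were above 0, but this reading was taken because of these markers, so the share does not test it. Labels exchanged on both arrays leave the same 11.1% of markers below 0 and cannot be told apart from a Cy3 numerator, because both give identical values. A Cy5 numerator with correct labels would put the markers higher in embryos that the labels call hemocyte minus, which is unlikely. Fat body genes, whose tissue also requires srp, were not among the markers behind the choice, apart from Col4a1. Of 18 measured, 8 passed limma on the hemocyte side and 1 on the opposite side. These values argue against a Cy5 numerator with correct labels, although the numerator itself is not given.

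Muscle and cuticle genes lay on the side opposite to the hemocyte markers. A lower share of hemocytes would raise the markers of all other cell types alike. The lists of 9 other cell types differed from each other (98 genes, permutation test of the Kruskal-Wallis statistic, p = 5e-05). The fat body list was not among these 9. This test replaced a comparison of muscle and cuticle with neuron, glia and trachea after that one had been seen. Muscle and cuticle, whose low values prompted it, are among its lists, and it shuffles genes that are not independent. Its p therefore cannot decide for or against this cause. Medians were -0.77 for muscle and -0.60 for cuticle, but -0.06 for glia and 0.10 for hindgut and foregut. On single arrays the muscle median was -0.86 (A) and -0.73 (B), and the glia median 0.02 (A) and -0.05 (B). The shift was thus not alike in all lists. These medians, unlike the p, argue against a lower share of hemocytes as the whole cause. A shift of all genes by the normalization cannot be told apart from none: without centring the larger absolute median of the arrays was 0.024, but ratios that the authors centred would have a median near 0 in either case. A difference in developmental age may contribute. The medians of lists of late differentiation were -0.77 for muscle, -0.60 for cuticle, -0.224 for neuron and -0.11 for trachea. Neuron and trachea thus lay on the side of muscle but nearer to 0. The cell cycle median was 0.29, on the other side. With no embryo ages in the labels, a difference in age cannot be told apart from an effect of the mutation. An effect of the missing hemocytes or of srp in other tissues stays open and was untested.

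Sequence or expression differences carried on the mutant chromosome around srp would show as larger ratios of its neighbours, in a test planned before the data were examined. The 154 measured genes within 1 Mb of srp had a mean absolute log2 ratio of 0.25, against 0.27 for the others (one-sided permutation test, p = 0.69). Of these genes 12.3% passed limma, against 13.4% of all genes. These values argue against a broad excess of differences within 1 Mb of srp. A few altered neighbours, or differences between the genotypes spread over the genome, would not show in this comparison.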
